A study of Oryza sativa with 6 samples.

How the data were processed

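Root RNA of the rice (Oryza sativa) varieties Prasanna and Varadan was measured on 6 biotin-labelled Affymetrix rice arrays, 1 array per sample. Per the labels, 1 array of each variety came from seedlings without nitrogen and 2 from seedlings with supplemented nitrogen. The series' design text names 2 replicates of each; the second arrays without nitrogen were not analysed here. Only the number 2 of a replicate stands in the labels, so the number 1 used here is only a name. Each probe set's value is a MAS5 signal, the standard single-array summary of Affymetrix, per the submitters' processing notes; its version, the image analysis and the detection settings are not given in the sources used here.

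The deposited log2 table holds 1 log2 signal per probe set and array, and its values were used as deposited. The deposited series matrix holds the same signals as linear intensity values, per the labels and the values themselves. On the linear scale the mean of every array after trimming 2% at each end was 500, so the arrays had been scaled to 1 level before deposit. The tables agreed to within 1e-06 on the log2 scale for 4 arrays by name. The other two columns, the Varadan array without nitrogen and the Varadan array with nitrogen, replicate 1, were exchanged between the tables. No source says which table is right. The log2 table, chosen as the main one before the data were examined, was kept, and the series matrix was run as an alternative. Scaling of this kind fixes the mean of the bright probe sets, so a shift shared by most genes would not be seen. MAS5 does not pool information between arrays, which makes low signals noisy. The deposited tables were used without detection calls, so signal over background was judged only by level. Readings of a named gene below the 40th percentile of their array (4.89 to 5.42 log2) were not taken as above background. A difference that rests on such a reading is given as a bound ("at least", or "or lower"), with these readings raised to that percentile and without an SE; which genes to bound was settled after seeing the data. Adjusted p-values are those of the deposited values.

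Of 57381 probe sets on each array, 187 controls were left out. The tests ran on the 34316 probe sets whose mean log2 value over the 6 arrays lay at or above the 40th percentile. Gene identifiers came from the platform annotation: 34860 probe sets had 1 gene, 567 had several and 21767 had none. No gene was named from a probe set with several. Among the tested probe sets 27443 had 1 gene, for 21680 genes in all. Genes of the fixed lists carry the name in the list. Other gene names came from the synonyms of a reference gene table (assembly ASM3414082v1), in which 30586 probe sets with 1 gene found an entry. In all, 3332 tested probe sets had a name that is printed here. No genome sequence was used, so no positions are given. Of several probe sets of a gene, the one with the highest mean over the 6 arrays was used.

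Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on level), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all tested probe sets. The nitrogen response in both varieties (2 arrays without nitrogen against 4 with it) and the variety difference over both nitrogen supplies (3 arrays against 3) came from an additive model of variety and nitrogen supply. The spread in the additive model includes the difference of response between the varieties. Genes that respond differently in the varieties therefore pass less easily there. The nitrogen response within a variety, the difference of the responses and the variety difference with supplemented nitrogen came from a model with 1 mean per variety and supply. In that model the spread comes from the replicate pairs with nitrogen, and each lone array without nitrogen is assumed to vary like the others. Errors are the standard errors (SE) of the model unless an SD is named. All p-values of genes and lists are from limma. The number of arrays limits the precision.

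Gene lists were fixed by locus: 20 lists with 207 genes, of which 190 had a probe set of their own and 187 were tested. The names of 125 of the genes on the array matched a synonym in the reference table. For the loci Os02g0620500 and Os02g0620600, called OsAMT1.2 and OsAMT1.3 here, the synonyms conflict. Both loci have AMT1-2 and AMT1-3 as synonyms, but the names starting with Os are the other way round. The 19 lists with at least 3 tested members were nitrate uptake and transport, ammonium and urea transport, nitrogen assimilation, nitrogen-responsive regulators, amino acid transport, phosphate starvation, iron acquisition, photosynthesis, low oxygen and fermentation, pathogenesis-related and defence, diterpenoid phytoalexins, phenylpropanoid and lignin, cell cycle, cytokinin response and turnover, auxin transport, strigolactone synthesis and signalling, abscisic acid and dehydration, autophagy, and aquaporins. The root hair list had 1 tested member, OsCSLD1, at a nitrogen response of -1.10 ± 0.39 log2, and was not tested. The photosynthesis and cell cycle lists stand for green tissue and for dividing root tips. Lists were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Another 12 lists defined by gene descriptions were not run, since the tables used here hold no descriptions.

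The lists, designs, filter and alternatives were fixed before the data were examined. So was the rule for the genes named: the 10 largest rises and falls among genes past the threshold, filled where fewer pass by the smallest p and then given as not past it, the up to 4 members of each list with the largest moderated statistic, and 11 nitrogen genes whatever their values. For the nitrogen response in both varieties, each array without nitrogen also had to lie beyond both arrays with nitrogen of its own variety. Alternatives were the series matrix, quantile normalization, centring on the median, no filter, a 60th percentile filter, a floor at the 40th percentile, leaving out each array in turn, 2 other variance models, 1 probe set per gene, and other designs and sizes. With an array lacking nitrogen left out, the additive model gave the nitrogen response of the other variety alone. Its variety difference then came from the arrays with nitrogen alone. The series matrix without the array it names Varadan with nitrogen, replicate 1, was added after seeing the data.

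The tests were tried on simulated data with 50 probe sets changed at each of 4 sizes among 34316. For the nitrogen response in both varieties 44% of probe sets changed by 2 log2 were recovered, and 5 unchanged ones were called. Without the array labelled Varadan with nitrogen, replicate 1, these values were 62% and 14. For the variety difference over both supplies they were 44% and 7, with supplemented nitrogen 40% and 11. For the response within a variety they were 28% and 16 in Prasanna and 18% and 9 in Varadan. For the difference of the responses no probe set changed by 2 log2 was recovered, and 48% of those changed by 4 log2 were. With 5 arrays the model with 1 mean per group called 196 unchanged probe sets for Prasanna and 56 for Varadan, and 46 for the variety difference with nitrogen, so its counts are given with that limit. A list shifted by 1 log2 was past the threshold in every comparison; of the 19 lists without a shift, 2 were past it in the variety difference over both supplies and 0 in the other comparisons of all 6 arrays. Without the array labelled Varadan with nitrogen, replicate 1, 1 was past it in the nitrogen response in both varieties, 2 in the variety difference over both supplies and 0 in the others. Beside a shifted list, up to 3 others were past it on those 5 arrays. These list trials used the preset correlation, and their noise was drawn independently for each probe set. They therefore cannot show how often lists of correlated genes without a shift would pass. Whether a shifted list would pass with an estimated correlation was not tried, so failure there does not tell correlation from too few arrays.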

Results

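The 6 arrays compared roots of 14-day-old rice seedlings of the varieties Prasanna and Varadan, grown in hydroponics with or without nitrogen. Per the labels, seedlings germinated for 7 days and then grew for 10 days in Yoshida medium, a rice nutrient solution, with nitrogen before the supply was split. These 7 and 10 days add up to more than the 14 days given as the age, and no label settles this. Each variety had 1 array without nitrogen and 2 arrays with it. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The median log2 signal over all probe sets lay between 5.59 and 6.11 on the 6 arrays. The replicates with nitrogen correlated at r = 0.925 across probe sets in Prasanna and 0.909 in Varadan; 5848 and 7741 probe sets differed at least 2-fold within these pairs.

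Genes of nitrogen uptake separated the arrays, but not wholly by their labels. OsNRT2.3 (Os01g0704100), a high-affinity nitrate transporter, stood at 11.31 log2 without nitrogen and at 6.82 and 7.06 with it in Prasanna. In Varadan it stood at 12.49 without nitrogen, at 12.29 on the array labelled with nitrogen, replicate 1, and at 7.78 on replicate 2. OsAMT1.2 (Os02g0620500), an ammonium transporter, read 10.83, 10.78 and 4.41 on the same Varadan arrays, and 9.54 without nitrogen and at most 6.40 with it in Prasanna. OsNiR (Os01g0357100), the nitrite reductase, went the other way, at 11.26, 10.73 and 14.31 in Varadan and 9.98, 13.41 and 13.93 in Prasanna. The array labelled Varadan with nitrogen, replicate 1, held these genes near the levels without nitrogen, and it is called the doubtful array from here on. Its column and that of the Varadan array without nitrogen were exchanged between the deposited tables, so which of the 2 arrays had which label is not settled either. Both lay at such levels, and the exchange alone does not give Varadan a pair of arrays with nitrogen that match. By correlation over all tested probe sets, the doubtful array lay closest to replicate 2 of Varadan (r = 0.909). They differed at least 2-fold in 7741 probe sets. With the Varadan array without nitrogen the doubtful array correlated at 0.895 (8505 probe sets). The Varadan array without nitrogen and replicate 2 correlated at 0.866 (11686). The doubt thus came from the nitrogen genes and not from these correlations. Every group below follows the labels of the log2 table.

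**Figure D1:**
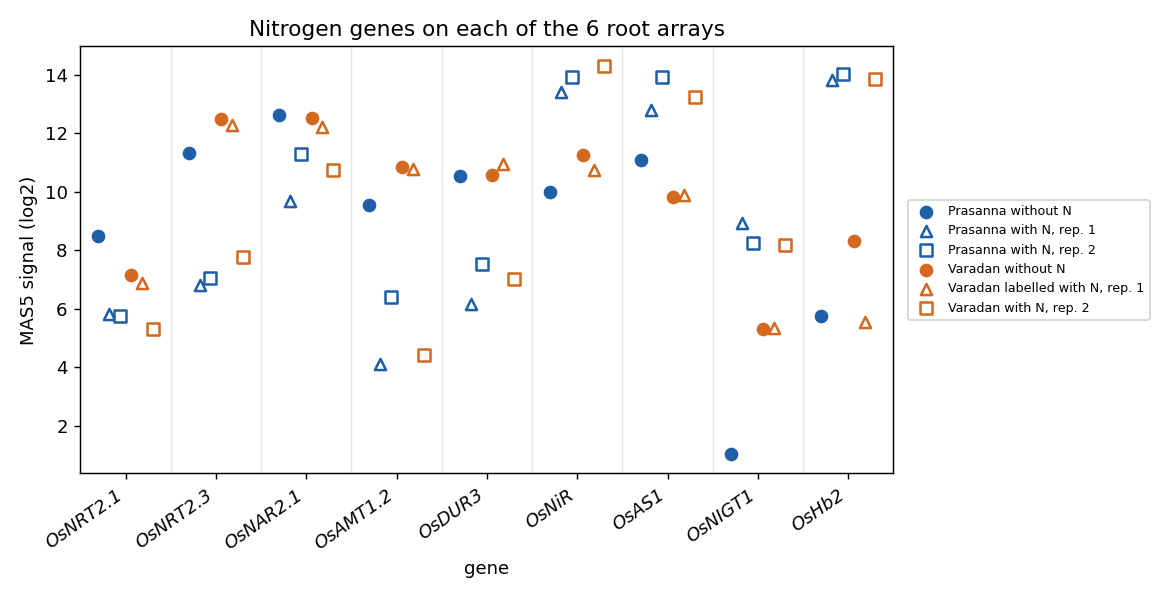
MAS5 signal (log2, vertical axis) of 9 nitrogen genes (horizontal axis) on each of the 6 root arrays, 1 point per array; filled circles are arrays without nitrogen, open symbols arrays labelled with nitrogen, blue Prasanna and orange Varadan. For OsNRT2.3 the array labelled Varadan with nitrogen, replicate 1, sits at 12.29, beside the Varadan array without nitrogen at 12.49.

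Other features also set arrays apart. The mean of the 14 photosynthesis genes, markers of green tissue, was 11.25, 11.04 and 10.54 in Prasanna (without nitrogen, then replicates 1 and 2 with it) and 13.07, 12.24 and 11.17 in Varadan. The mean of the 9 cell cycle genes, markers of dividing root tips, was 9.74, 9.67 and 10.33 in Prasanna and 9.69, 10.39 and 10.18 in Varadan. Bacillus spike-in RNA read 10.96, 10.99 and 9.87 in Prasanna and 11.04, 9.53 and 7.84 in Varadan. A control probe set named for EF1a of the blast fungus Magnaporthe read 7.28, 7.68 and 8.50 in Prasanna. In Varadan it read 9.50, 7.57 and 10.23. What gave this signal, and whether it bears on the defence and phytoalexin lists, was not tested. The 3' minus 5' difference of GAPDH, a sign of RNA quality, was 3.06 to 3.52 in Prasanna and 4.38 to 4.77 in Varadan. Those of actin (5.15 to 5.23 in Prasanna, 5.15 to 5.82 in Varadan) and cyclophilin (1.39 to 1.54 and 1.34 to 1.83) overlapped between the varieties.

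**Figure D2:**
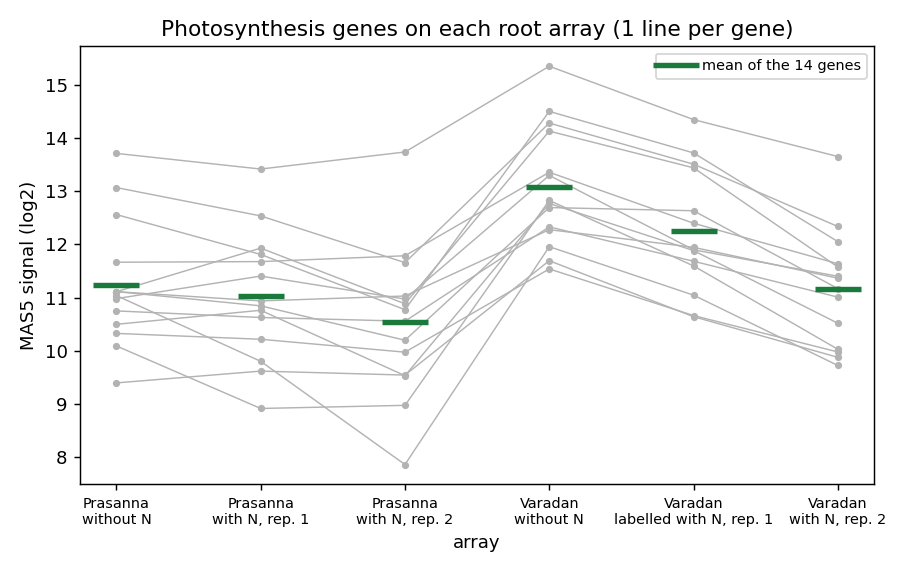
MAS5 signal (log2, vertical axis) of the 14 photosynthesis genes on each of the 6 root arrays (horizontal axis), 1 grey line per gene, with the mean of the 14 as a green bar. The mean is highest on the Varadan array without nitrogen, at 13.1, and lowest on replicate 2 of Prasanna with nitrogen, at 10.5.

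The first comparison asked how roots of both varieties responded to the lack of nitrogen (2 arrays against 4). Over all 6 arrays 8 of 19 gene lists were higher without nitrogen in limma's camera test. Nitrate transport (12 genes, median 0.99 log2, 10 higher) had an adjusted p = 0.00236, and ammonium and urea transport (10 genes, median 1.09, 8 higher) one of 0.0317. Phenylpropanoid and lignin synthesis (9 genes, median 1.13, 8 higher) had 0.000119, and abscisic acid and dehydration (6 genes, median 2.17, 5 higher) had 0.0022. Photosynthesis (14 genes, all higher, median 0.72) had 0.000119, diterpenoid phytoalexins (11 genes, 10 higher, median 0.91) 0.016, defence (9 genes, 8 higher, median 0.64) 0.0308 and aquaporins (11 genes, 9 higher, median 0.34) 0.0308. No list passed with an estimated correlation: there the adjusted p was 0.58 for defence and phytoalexins and 0.556 for the other 6. The photosynthesis mean was itself highest on the Varadan array without nitrogen. Leaving out 1 array ended several calls. With an array lacking nitrogen left out, the test was of the other variety's response alone. Ammonium transport fell out without the Prasanna array lacking nitrogen (adjusted p = 0.196) or replicate 1 of Prasanna with nitrogen (0.109). Without the Varadan array lacking nitrogen, 4 lists remained past the threshold, and photosynthesis (0.194), phytoalexins (0.891), defence (0.852) and aquaporins (0.292) did not pass. Without the doubtful array phytoalexins (0.148), defence (0.204) and aquaporins (0.238) did not pass. The nitrate, phenylpropanoid and dehydration lists passed in each of the 6 cases.

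Single genes did not pass over all 6 arrays. Limma called 0 probe sets (smallest adjusted p = 0.123), with 7420 at an unadjusted p under 0.05 (2943 higher, 4477 lower) where chance alone would give 1716. The additive fits without trend or with a robust variance, and the fit with group means, also called 0. The smallest p among named genes with higher signal belonged to RAB16D (Os11g0453900), a dehydrin (3.08 ± 0.41), OsC3H33 (1.03 ± 0.15), OsMSRA2.1 (0.89 ± 0.14), OsTIP4.1 (1.24 ± 0.20) and OsAAP5 (1.61 ± 0.26). OsMIF2 (-1.99 ± 0.23), AP25 (-1.77 ± 0.25), ARF5 (-2.23 ± 0.33), OsCslF8 (-1.97 ± 0.30) and OsGSK2 (-1.21 ± 0.19) led those with lower signal. The remaining named genes read 1.21 for CML27, 2.11 for OsHox22, 0.78 for OsSUMO1, 1.24 for OsOPR5, 0.96 for GRXS2, -2.67 for ML3, -1.08 for OsAGO4b, -2.02 for OsZHD10, -1.12 for OsC3H53 (its other probe set -0.16) and -1.13 for OsVTE2-1, whose 5 other probe sets ran from -1.25 to 1.19. Adjusted over the list alone, 7 nitrate genes were higher, 7 phenylpropanoid genes, 5 dehydration genes, 2 defence genes, 2 amino acid transporters and 1 gene each of phytoalexins and aquaporins, against 0 of each over all genes tested. In the series matrix, where the doubtful and the lone Varadan array trade places, limma also called 0 (2311 at an unadjusted p under 0.05) and 8 lists passed, 4 higher and 4 lower. There the nitrate (0.00606), ammonium (0.0104), phenylpropanoid (0.00606) and dehydration (0.0141) lists were higher, assimilation (0.00606) and iron acquisition (0.00225) were lower, and defence (0.00225) and phytoalexins (0.00488) turned lower too.

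Without the doubtful array (2 arrays against 3), 4616 probe sets passed, 2044 higher and 2572 lower without nitrogen. That array was doubted for its nitrogen genes, so this count is not an independent test of them. OsNRT2.3 rose by 4.52 ± 0.22 log2 (22.9-fold, adjusted p = 0.000552), OsNRT2.1 (Os02g0112100) by 2.34 ± 0.45 (0.0196), and OsNAR2.1 (Os02g0595900), the partner protein of these transporters, by 1.97 ± 0.43 (0.0282). OsAMT1.2 rose by at least 4.69 (0.00909) and OsDUR3 (Os10g0580400), a urea transporter, by 3.64 ± 0.41 (0.00384). OsNiR fell by 3.42 ± 0.23 (0.000753), OsAS1 (Os03g0291500), an asparagine synthetase, by 2.76 ± 0.38 (0.00712) and OsNIGT1 (Os02g0325600), a nitrate-inducible repressor, fell too (-3.16 or lower, 0.0154). The haemoglobin genes OsHb2 (-7.04 ± 0.52) and OsHb1 (-3.96 ± 0.52) fell as well. These sizes moved with the array left out. Without the Prasanna array lacking nitrogen, and with the doubtful array kept, the fit gave the response of Varadan alone. There OsHb1 read 0.0861, OsHb2 -1.37, OsNRT2.3 2.46, OsNRT2.1 1.07, OsNAR2.1 1.04, OsAMT1.2 at least 2.96 and OsDUR3 1.59. OsNiR read -1.26, OsAS1 -1.73 and OsNIGT1 -1.34 or lower. Without the Varadan array lacking nitrogen the fit gave the response of Prasanna alone, with OsHb1 at -5.10 and OsHb2 at -8.18. Without replicate 2 of Varadan OsAMT1.2 read at least 2.198, OsNRT2.3 2.59, OsDUR3 1.96, OsNiR -1.89 and OsAS1 -1.33. There OsHb1 read -1.80, OsHb2 -3.48 and OsNIGT1 -1.93 or lower. Without replicate 1 of Prasanna OsHb1 read -2.08, OsHb2 -4.33, OsNAR2.1 1.15, OsDUR3 2.201, OsNIGT1 -2.10 or lower and OsAMT1.2 at least 3.04. Leaving out replicate 2 of Prasanna, OsHb1 read -2.19, OsHb2 -4.25, OsNiR -2.19 and OsAS1 -1.72. With the doubtful array kept, none of these genes passed over all 6 arrays. In the series matrix without its own array of that name, 2880 probe sets passed; 2518 passed in both with the same direction, where independent lists would share 193, but the inputs share 4 of 5 arrays. Each fit had 1 array with nitrogen in Varadan.

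Without the doubtful array the lists gave more detail. Of 12 nitrate genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera 0.0011, adjusted p = 0.555 with an estimated correlation): OsNPF2.4 rose (1.38), OsNAR2.2 (at least 1.61) and OsPTR6 (0.88) too. Of 10 ammonium and urea genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; 0.00398, adjusted p = 0.663 with an estimated correlation): OsAMT3.3 (at least 2.74) and OsAMT1.1 (1.44) rose, OsAMT2.3 fell (-2.23 or lower), and OsAMT1.3 read 0.87 (adjusted p = 0.0656). Of 9 phenylpropanoid genes 8 rose over all genes and over the list alone (1.4e-05, adjusted p = 0.555 with an estimated correlation), among them the phenylalanine ammonia-lyase OsPAL2 (1.78 ± 0.17), OsC4H (1.60), OsCAD2 (1.22) and OsCOMT (0.93). Of 6 dehydration genes 5 rose by both counts (0.00145, adjusted p = 0.663 with an estimated correlation): RAB16D (3.31), RAB16B (3.42), OsLEA3 (2.59) and OsbZIP23 (1.37). Of 14 iron acquisition genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; 0.0167, adjusted p = 0.663 with an estimated correlation): OsNRAMP1 (-1.49), OsENA1 (-1.62) and OsTOM1 (-0.84) fell and OsIRT1 rose (0.69). Of 14 photosynthesis genes 4 rose (5 over the list alone; 0.000172, adjusted p = 0.7 with an estimated correlation): LhcbA (1.85), OsPsbS1 (2.22), OsRCA (1.39) and OsRBCS2 (1.77). Sizes of these genes moved with the array left out while the doubtful array was kept. Values without an array lacking nitrogen are again the response of the other variety alone. Without the Prasanna array lacking nitrogen OsNPF2.4 read 0.77, OsAMT3.3 1.37, OsAMT1.1 0.64, OsC4H 0.83, OsLEA3 1.09, RAB16B 2.17, OsbZIP23 0.75, OsNRAMP1 -0.96 and OsTOM1 -0.50. Leaving out replicate 2 of Varadan, OsAMT3.3 read at least 1.69, OsAMT1.1 0.87, OsAMT2.3 -1.45 or lower, OsPAL2 1.18, OsNRAMP1 -0.90, OsENA1 -0.98, LhcbA 1.18, OsRBCS2 1.06 and OsRCA 0.89. Without the Varadan array lacking nitrogen OsPTR6 read 0.52 and LhcbA 1.15, and without replicate 2 of Prasanna OsAMT3.3 read 1.97, RAB16B 2.26 and OsPsbS1 1.43. Fry, adjusted over the lists, passed nitrate transport (0.0309), phenylpropanoids (0.00718) and amino acid transport (0.037); over all 6 arrays it passed amino acid transport alone (0.0234).

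The other lists did not pass camera on those 5 arrays. Of 17 assimilation genes (adjusted p = 0.175) 7 fell and 1 rose by both counts: OsAlaAT (-1.49), OsGDH1 and OsNADH-GOGAT1 (Os01g0681900; -1.11) fell besides OsNiR and OsAS1, and OsGS1.1 rose (1.64). OsGS1.2 (Os03g0223400) read 0.04 ± 0.18, and OsNIA1 (Os08g0468100), a nitrate reductase, -0.75 ± 0.51. Of 15 regulators (0.14) 5 fell and 2 rose (6 and 2 adjusted over the list alone): OsNLP5 (-1.24) fell, OsNLP1 rose (2.04), OsNLP3 read -0.48 and OsLBD37 (Os07g0589000) -0.32. Low oxygen and fermentation (0.807) had 3 of 11 genes higher and 3 lower (3 and 4 adjusted over the list alone): OsPDC1 (at least 3.43) and OsLDH (1.12) rose, OsSUS1 fell (-0.95; its other probe sets ran from -0.98 to 1.15 over all arrays) and OsALDH2a read -2.06 or lower. OsAAP5 (1.82) and OsAAP1 (2.04) rose, OsAAP6 (-1.28) fell and OsLHT1 read -0.30 among 5 amino acid transporters (0.281). OsMCM2 (-1.03) was the 1 of 9 cell cycle genes that fell (0.302; 2 adjusted over the list alone), while OsMCM6 read -1.20. Of 4 auxin transporters OsPIN2 (-1.11) fell (0.148), OsPIN1b read -0.58 and OsPIN1a -0.29; OsPIN10a read -0.96 or lower, though another probe set of it read 1.67 over all arrays. PBZ1 (1.13) and OsPR1b (1.85) rose among 9 defence genes, OsMAS (1.43) among 11 phytoalexin genes, OsPIP2.3 (0.75) among 11 aquaporins, where OsTIP2.2 fell (-1.38). OsSPX2 (1.31) rose among 12 phosphate genes (0.488), D10 (at least 2.16) among 5 strigolactone genes (0.653) and OsATG8b (0.64) among 3 autophagy genes (0.281); these counts were equal adjusted over the list alone. No cytokinin gene passed (0.807), with OsRR2 at -1.07, OsCKX5 at 0.84, OsCKX4 at 0.51 and OsRR3 at -0.51. Here too sizes moved while the doubtful array was kept, and values without an array lacking nitrogen are the response of the other variety alone. Without the Prasanna array lacking nitrogen OsAAP6 read -0.0219, OsAAP1 1.31, OsGS1.1 1.04, OsGDH1 -0.48, OsNLP1 0.95, OsMAS 2.24, OsTIP2.2 -0.54, OsSPX2 0.76 and D10 0.54. With replicate 2 of Varadan left out OsAAP6 read -0.58, OsAAP1 1.18, OsGS1.1 0.96, OsAlaAT -0.98, OsGDH1 -0.60, OsNADH-GOGAT1 -0.65, OsNLP1 1.002, OsTIP2.2 -0.84, OsSPX2 0.54, OsATG8b 0.34 and OsPDC1 at least 2.74. Without the Varadan array lacking nitrogen OsPDC1 read at least 1.58, OsPIN2 -0.73, OsPR1b 1.22 and OsMAS 0.94. With replicate 2 of Prasanna left out OsAAP6 read -0.59, OsGDH1 -0.66, OsNADH-GOGAT1 -0.73, OsNLP1 1.32, OsTIP2.2 -0.87 and OsSPX2 0.85, and without replicate 1 OsAAP6 read -0.82 and D10 1.46.

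Named genes outside the lists also changed on these 5 arrays. OsALN, an allantoinase, rose by at least 4.63, OsHCT4 by 4.43 ± 0.20, OsAT10 by at least 3.22, CYP71Z6 by at least 2.56, OsPP108 by 3.80 and OsHsf-16 by 3.67. OsCIN5 (-4.27 ± 0.31), GRXC10 (-2.06 or lower), GRXC1 (-4.15), OsAHT1 (-1.77 or lower), OsCIPK10 (-3.48) and ML3 (-3.05) fell. In Varadan alone, without the Prasanna array lacking nitrogen and with the doubtful array kept, GRXC10 read -0.26, GRXC1 -0.33, OsALN 1.94 and OsHCT4 2.58. There OsPP108 read 2.31, OsHsf-16 1.78, CYP71Z6 2.24, OsCIN5 -2.63, OsAHT1 -0.76 or lower and OsCIPK10 -2.23. In Prasanna alone, without the Varadan array lacking nitrogen, GRXC1 read -5.65 and OsAT10 2.41. Without replicate 2 of Varadan OsCIN5 read -2.18, OsAT10 1.59, OsHCT4 2.62, OsHsf-16 2.23, GRXC1 -2.59, GRXC10 -0.14 or lower, OsAHT1 -0.96 or lower and OsALN at least 3.09. Without replicates 1 and 2 of Prasanna in turn GRXC1 read -2.59 and -2.63, and GRXC10 -1.30 and -0.47 or lower; without replicate 1 OsAHT1 read -0.99 or lower.

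Over all 6 arrays the lists that did not pass were assimilation (adjusted p = 0.578), regulators (0.222), amino acid transport (0.238), phosphate starvation (0.49), iron acquisition (0.222), low oxygen (0.56), cell cycle (0.117), cytokinin (0.588), auxin transport (0.0644), strigolactone (0.56) and autophagy (0.386). Auxin transport and cell cycle passed, lower, without the Prasanna array lacking nitrogen or without replicate 1 of Prasanna with nitrogen, and iron acquisition without the doubtful array. The low oxygen test pointed up with a median of 0.03 and a mean of -0.28, and the strigolactone test up with a median of -0.21 and a mean of 0.34. Members of these lists read as follows: OsPT8 (-0.46), OsSPX6 (at least 1.34), OsPT1 (0.58) and OsSPX2 (0.90) of phosphate starvation, and OsMAX1e (0.76), D14 (-0.24) and D17 (-0.34) of strigolactone. Of autophagy, OsATG8a and OsATG8c read 0.04 each. OsCPS2 (1.47), CYP76M7 (0.98) and CYP76M8 (0.91) of the phytoalexins, OsPR10b (0.92) and RSOsPR10 (0.85) of defence, and OsTIP2.1 (0.57) and OsPIP2.2 (0.34) of the aquaporins did not pass either. Centring each array on its median moved the median response of all probe sets to -0.31 (from about 0), so directions of changes smaller than this depend on the scaling: OsATG8a, OsATG8c and OsGS1.2 turned negative.

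Within varieties, a lone array without nitrogen was set against 2 with it. In Prasanna the nitrate (adjusted p = 0.000508), ammonium (0.0397), phenylpropanoid (0.000149) and dehydration (0.000149) lists were higher without nitrogen, each at adjusted p = 0.673 with an estimated correlation. OsNAR2.2 read at least 1.51 log2, OsLEA3 3.31 ± 0.53, OsNIA1 -1.88 ± 0.20 and OsNIGT1 -3.45 or lower. In Varadan the photosynthesis (8.91e-08), phytoalexin (3.33e-06), defence (9.03e-05), phenylpropanoid (0.0015), aquaporin (0.00296), nitrate (0.0316) and dehydration (0.0378) lists were higher, and auxin transport (0.0213) and cell cycle (0.0418) lower, at adjusted p of 0.59 to 0.609 with an estimated correlation. OsTBT2 read 4.15 ± 0.49, OsMAS 2.24 ± 0.33, OsCKX3, a cytokinin oxidase, -2.57 or lower and OsORC1 -2.57 ± 0.33. In the series matrix the defence (6.29e-11) and phytoalexin (1.96e-08) lists of Varadan were lower instead. Limma called 0 probe sets in Prasanna (3984 at an unadjusted p under 0.05) and 0 in Varadan (4381), as did the other variance models. Without the doubtful array it called 171 in Prasanna and 241 in Varadan, and 139 in Prasanna without replicate 2 of Varadan. In simulated data of that design 196 and 56 unchanged probe sets were called, so no gene is named from these counts.

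Named genes of Prasanna that did not pass also included RAB16D (3.46), OsC3H33 (1.18), OrysaZ1 (1.70), GST-I (2.59), OsTIP4.1 (2.82-fold higher), OsINO1-1 (2.04), OsADF3 (1.93), OsNramp5 (1.16), OsRDR4 (-1.24 or lower), OsCslF8 (-2.42), OsMIF2 (-2.06), LOGL4 (-3.01), GLP2 (-1.60), GRXC14 (-2.16 or lower), a chitinase (Os10g0416100; -1.34) and OsKO5 (-2.25). Those of Varadan included PRXIIE-2 (2.48), OsPIP2.3 (0.95), OsJAZ1 (Os10g0392400; 4.93-fold higher), CML27 (1.46), GRXS2 (1.18), OsPsbO (1.65), DREB1G (at least 3.67), OsPTR6 (1.24), KIN12F (-3.15 or lower), OsAPY3 (-1.77), OsFH6 (-1.16 or lower), OsBURP12 (-1.66 or lower), PCF6 (-2.34 or lower), AP25 (-2.10), OsAGO17 (-0.56 or lower) and OsAGP1 (-1.52).

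Whether the varieties responded differently, which the series title raises, was tested as Varadan's response minus Prasanna's. In 6 lists this difference passed: photosynthesis (median 0.93, adjusted p = 6.12e-05), diterpenoid phytoalexins (1.68, 3.89e-06), defence (1.43, 0.000148), nitrogen assimilation (0.55, 0.00221) and aquaporins (0.50, 0.0194) were higher in Varadan's response, and dehydration (-1.48, 0.0153) lower. With an estimated correlation none passed, at adjusted p = 0.711 for photosynthesis and 0.585 for the other 5. OsNIA1 came first among the named genes: without nitrogen it read -1.88 in Prasanna and 0.71 in Varadan, a difference of 2.60 ± 0.29 (limma, adjusted p = 0.925). CYP99A3 of the phytoalexins read 2.08 ± 0.53 and OsPsbO of photosynthesis 1.85 ± 0.48, both named for their small p and above the medians of their lists. Adjusted over the list alone 1 assimilation gene passed, and 0 over all genes. Limma called 0 probe sets (1838 at an unadjusted p under 0.05 against 1716 by chance), and 0 without the doubtful array (2422). Aquaporins did not pass without replicate 2 of Prasanna (0.0615) or without the doubtful array (0.104), while cell cycle passed, lower, without replicate 2 of Prasanna (0.0122) and iron acquisition, higher, without replicate 1 of Prasanna (0.0101). Without replicate 2 of Varadan 10 lists passed, iron acquisition (0.00123) among them. In the series matrix defence (1.87e-05), phytoalexins (0.000286) and aquaporins (0.0453) were lower in Varadan's response, opposite to the above. Nitrate (0.0113), phenylpropanoids (0.000286) and dehydration (0.000215) were also lower there and cell cycle (0.0453) higher, while photosynthesis and assimilation did not pass.

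Other named genes of this difference, none past the threshold, were OsRDR4 (at least 1.68), OsKO5 (3.43), OsHAP5C (2.71), LP02 (1.74), LOGL4 (3.14), OsPsbO (4 other probe sets from -0.83 to 2.06), IAA19 (1.51) and OsTBT2 (2.60). On the lower side stood OsCKX3 (-1.49 or lower), OsAPY3 (-1.97), OsFH6 (-0.71 or lower; its other probe set 0.20), Os8N3 (-3.37), OsBURP12 (-1.43 or lower), KIN12F (-2.14 or lower), OsCAX1b (-2.38 or lower), PCF6 (-2.01 or lower), GST-I (-2.64) and OsAGP1 (-1.48). The list tests of amino acid transport and low oxygen pointed up with medians of -0.35 and -0.20. Centring on the median moved the median difference of all probe sets to -0.40.

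Across probe sets the responses of the varieties correlated at r = 0.253, and the replicate differences of the varieties at -0.00117; probe sets are not independent replicates. At least 2-fold changes against both arrays with nitrogen went the same way in both varieties for 855 probe sets (396 higher, 459 lower) and opposite ways for 344, where independent responses would give 411 of each. Differences between replicates alone gave 1117 and 1096, by a looser rule that needed only 1 pair of arrays per variety. Leaving out an array with nitrogen also loosened the rule, since its variety then needed a change against 1 array only. Without the doubtful array the counts were 2788 the same way (916 by independence) and 553 opposite. They were 1499 and 639 without replicate 1 of Prasanna and 1365 and 696 without replicate 2. Without replicate 2 of Varadan the opposite count was 811 and r was 0.0856. The balance of higher and lower among probe sets changed the same way depended on the setting: quantile normalization gave 323 higher and 568 lower, median centring 145 and 1027, and the series matrix 129 and 322. The floor gave 348 and 239, no filter 1689 and 982, leaving out the doubtful array 1514 and 1274, and replicate 1 of Prasanna 841 and 658.

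The varieties were also compared over both nitrogen supplies (3 arrays against 3), and 3 of 14 iron acquisition genes differed. OsIRT2 (Os03g0667300), an iron transporter, was higher in Varadan by at least 5.94 log2 (adjusted p = 0.00215). OsIRO2 (Os01g0952800), a regulator of the response to iron deficiency, was lower (-4.50 or lower, 0.00299), as was OsYSL2 (Os02g0649900), a metal-nicotianamine transporter (-6.57 or lower, 0.0143). As a list, iron acquisition did not pass (0.179), with 1 gene higher and 2 lower over all genes and 2 and 3 adjusted over the list alone. It passed, lower, without either array lacking nitrogen or without replicate 2 of Varadan. OsIRT1 (0.52) and OsYSL15 (-0.54), chosen after their values were seen, did not pass. OsNAR2.2 (Os04g0480200) was higher in Varadan by at least 2.84 (0.0149), OsPR1b, a pathogenesis-related gene, by 2.68 ± 0.43 (0.0343), and, also chosen after their values were seen, RAB16D by 2.19 ± 0.39 (0.0493) and OsADH1, an alcohol dehydrogenase, by 1.34 ± 0.19 (0.0195).

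**Figure D3:**
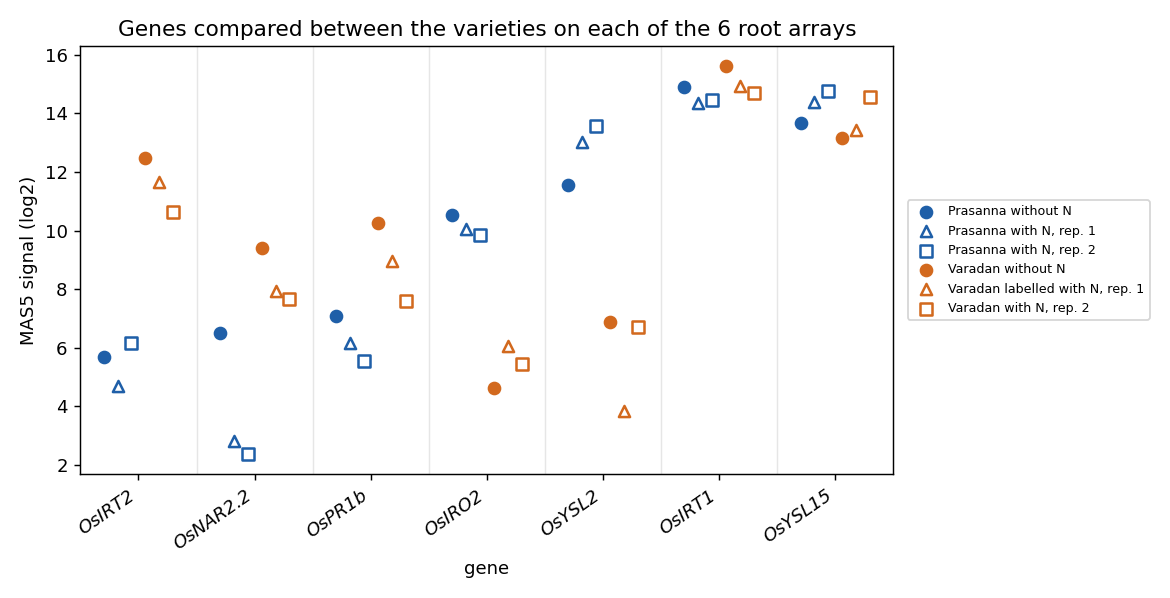
MAS5 signal (log2, vertical axis) of 7 genes (horizontal axis) on each of the 6 root arrays, 1 point per array; filled circles are arrays without nitrogen, open symbols arrays labelled with nitrogen, blue Prasanna and orange Varadan. OsIRT2 was higher in Varadan by at least 5.94 log2 and OsIRO2 lower (-4.50 or lower), while OsIRT1 (0.52) and OsYSL15 (-0.54) did not pass.

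Photosynthesis genes were all higher in Varadan (14 of 14, median 1.15, adjusted p = 3.16e-09; 11 adjusted over the list alone, 0 over all genes), at adjusted p = 0.747 with an estimated correlation. LhcbA read 2.16 ± 0.41 and OsRBCS2 1.71, and each of the 14 was highest on the Varadan array without nitrogen. Defence genes were higher as well (8 of 9, median 0.66, 0.0344; 2 adjusted over the list alone, 1 over all genes; adjusted p = 0.747 with an estimated correlation). That call ended without the Prasanna array lacking nitrogen (0.554), the Varadan array lacking nitrogen (0.562) or replicate 2 of Varadan (0.125). The photosynthesis call held with any 1 array left out. The other lists without iron acquisition had adjusted p of 0.0877 to 0.936; the count of lists was 4 without either array lacking nitrogen or without the doubtful array, with phytoalexins (0.0202) and cytokinin (lower, 0.0488) past the threshold in the last case. Fry passed amino acid transport alone (lower, 0.0301). In all, 601 probe sets passed, 326 higher and 275 lower in Varadan. Of the other splits of the arrays into 3 and 3, 1 had the most probe sets and lists past the threshold. It set the Varadan array lacking nitrogen, the doubtful array and the Prasanna array lacking nitrogen against the rest. With nitrogen supply in the model, it came down to the doubtful array against the other arrays with nitrogen.

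Further named genes higher in Varadan were OC-X (at least 4.46), OsWNK7 (3.72), OsASY1 (2.79), H2B.10 (2.75), MHX1 (2.73), OsMCM9 (2.49) and PRIN2 (2.23). Lower were OsKS2 (-2.76 or lower), OsPMEI28 (-3.11), GRXC15 (-2.72), SDH7 (-2.02), GRXS4 (-1.76; other probe sets 0.22 and 0.75), LOX1.1 (-1.59), OsHAK18 (-1.17) and OsCyp3 (-0.92). Of these 20 named genes OsIRT2, OsIRO2, OsWNK7 and H2B.10 passed with any 1 array left out. Probe sets of 1 gene could disagree: for the aquaporin OsTIP2.1 they read 1.76, 0.17 and -7.91 or lower, the last past the threshold (0.00268). With either array lacking nitrogen left out, the variety comparison rested on the arrays with nitrogen alone. The count was 264 without the Prasanna array lacking nitrogen, 256 and 239 without replicates 1 and 2 of Prasanna, 254 without the Varadan array lacking nitrogen, 399 without replicate 2 of Varadan and 820 without the doubtful array.

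With supplemented nitrogen (2 arrays against 2) OsIRT2 (at least 5.52), OC-X (at least 5.37), OsNAR2.2 (at least 2.81), OsWNK7 (3.91) and H2B.10 (2.87) were higher in Varadan, and OsYSL2 (-7.50 or lower), OsIRO2 (-4.19 ± 0.35) and SDH7 (-1.78) lower. The photosynthesis (adjusted p = 4.24e-05) and dehydration (0.00896) lists were higher and iron acquisition and aquaporins (0.0306 each) lower, all at adjusted p = 0.878 with an estimated correlation. Not past the threshold were OsOPR5 (2.02), Os8N3 (3.12), OsZIP3 (Os04g0613000; 2.42), OsMCM9 (2.56), OsASY1 (7.98-fold higher), LOX1.1 (-1.92), OsPMEI28 (-3.45), GRXS4 (-1.71), LOGL4 (-2.64), OsChia2a (-3.29; other probe sets -0.21 and 8.19), OsVIT1.2 (-1.41) and GLP2 (-1.42). Limma called 243 probe sets, 127 higher and 116 lower; 237 of them also passed over both supplies, each in the same direction. The doubtful array is 1 of the 4 here: without it 286 passed (46 unchanged ones were called in simulated data of that design), of which 36.0% were higher in Varadan against 52.3% with it, and defence (0.00705) was the list past the threshold in place of these 4. Without replicate 1 or 2 of Prasanna 0 passed, and without replicate 2 of Varadan 683 did. Without nitrogen each variety had 1 array, and the variety difference was not tested there. On these 2 arrays 4468 probe sets were at least 2-fold higher in Varadan and 3989 lower. Replicates with nitrogen already differed at least 2-fold in 5848 probe sets in Prasanna and 7741 in Varadan. So these counts do not measure a variety difference alone. Each of the 243 lay on the same side without nitrogen.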

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

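The tests of a wrong label and of green tissue were chosen only after the results were seen; the tests of RNA amount, of sequence variants and of other splits were planned before.

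The responses of the varieties to the lack of nitrogen differed in 6 gene lists by a test of the difference itself. These were diterpenoid phytoalexins (adjusted p = 3.89e-06), photosynthesis (6.12e-05), defence (0.000148), nitrogen assimilation (0.00221), abscisic acid and dehydration (0.0153, lower in Varadan's response) and aquaporins (0.0194). The test included the array labelled Varadan with nitrogen, replicate 1; aquaporins did not pass without it (0.104) or without replicate 2 of Prasanna (0.0615). With an estimated correlation none passed (0.585 to 0.711), and no probe set passed in limma (1838 at an unadjusted p under 0.05). In the series matrix defence, phytoalexins and aquaporins had the opposite direction, photosynthesis and assimilation did not pass, and dehydration passed in the same direction. With 1 array without nitrogen per variety, a difference between single samples and a difference between the varieties were not separated.

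The array labelled Varadan with nitrogen, replicate 1, had several nitrogen genes near the levels without nitrogen. OsNIA1 did not set it apart from replicate 2. For OsNIA1 the difference of the responses read 2.55 to 2.64 with any 1 array with nitrogen left out. By correlation over all tested probe sets this array lay closer to replicate 2 (r = 0.909) than to the Varadan array lacking nitrogen (0.895). Over 1506 probe sets changed at least 4-fold in Prasanna, chosen without any Varadan array, this array minus replicate 2 had the sign of the Prasanna response in 73.3%, and the Varadan array lacking nitrogen minus replicate 2 in 66.2%. A wrong label could give this, and the exchange of columns between the tables does not alter it. A difference in RNA amount was tested on the Prasanna replicates, whose spike-in levels differed by 1.13 log2 in the same order (1.69 in Varadan). They matched the sign of the Varadan response in 53.3% of 4034 probe sets, which gave no sign of it in Prasanna. These probe sets were chosen on the Varadan array lacking nitrogen and replicate 2, with spike-in levels of 11.04 and 7.84. A pair of another variety with a smaller spike-in difference cannot decide this for Varadan, so RNA amount stays open. A real difference in nitrogen state between Varadan cultures stays open too and was not tested.

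Photosynthesis genes were higher in Varadan in 14 of 14 cases. The test assumed that green tissue in the samples would raise all of them by about the same size, which was not itself tested. The SD over the genes divided by their median difference was 0.389 (SD 0.45, median 1.15), below the 0.5 set as the limit. The differences ran from 0.55 to 2.16 log2. A shared change in the roots could meet the same limit, so the test cannot tell the 2 apart. Green tissue in the Varadan roots could account for the list. A change of these genes in the roots themselves stays open and was not tested.

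Of the 601 probe sets that differed between varieties, sequence differences under the probes could account for a part. In 173 genes with a call and another tested probe set, the others moved in the direction of the call in 78.0%, with a median of 0.66 log2 against 2.77 for the calls. This lies between the bounds set before, so a sequence variant and a true difference cannot be told apart for these genes. The GAPDH 3' minus 5' difference also separated the varieties, while those of actin and cyclophilin overlapped. RNA quality was not tested as a cause of these calls.

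The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For probe sets, 1 split, the real one, had as many as 601, and the highest other had 82. For lists, all 10 splits had at least the real 2, and the highest other had 9, several times the real count. That split set the Prasanna and Varadan arrays lacking nitrogen and the array labelled Varadan with nitrogen, replicate 1, against the rest. Nitrogen supply was also in the model, so its counts came from that last array against the other arrays with nitrogen. They do not measure a structure shared with the arrays lacking nitrogen. The array labelled Varadan with nitrogen, replicate 1, had a photosynthesis mean of 12.24, against 11.04 and 10.54 in Prasanna with nitrogen and 11.17 on replicate 2 of Varadan. It also had the nitrogen gene levels above, and no test separated these.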

How the results depend on the processing

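The series matrix without the array it names Varadan with nitrogen, replicate 1, was chosen after seeing the data; the other alternatives were planned. Of the named genes' values under all alternatives, 2631 kept direction and side of the threshold, 107 passed it newly, 120 no longer passed and 65 reversed. Most of the 216 named results had not passed in the main setting, so keeping their side says little. In the variety difference 20 had passed over both supplies and 8 with supplemented nitrogen. Of these, 4 and 0 passed with any 1 array left out. Of the summary results 119 stayed within the spread or 1.5 times and 56 moved. The 119 include counts of 0 that stayed 0. The spread was the SD of the correlation over its own values with 1 array left out (0.112). For counts that tally compared size and not direction. In the series matrix the nitrogen response kept 8 lists, but as 4 higher and 4 lower instead of 8 higher. Quantile normalization, median centring, the other filters, the floor and the other variance models left the count of the nitrogen response at 0 in limma (7420 at an unadjusted p under 0.05 in the main setting). Leaving out 1 array gave 0 to 4616 for both varieties, 0 to 171 for Prasanna and 0 to 241 for Varadan, and 239 to 820 for the variety difference over both supplies. With supplemented nitrogen it gave 0 to 683. For lists it gave 4 to 9 in the nitrogen response, 5 to 10 in the difference of the responses and 2 to 4 in the variety difference. The correlation of the responses ranged from 0.0856 to 0.355, probe sets changed the same way from 1039 to 2788 and opposite ways from 553 to 811. The alternative chosen after seeing the data gave 2880, 327 and 55 for the nitrogen response in both, Prasanna and Varadan, 1099 for the variety difference and 2182 changed the same way. In the full series matrix the variety difference with nitrogen was 155, and 451 and 179 probe sets changed the same and opposite ways. Without trend the variety counts were 176 and 50 (over both supplies, then with nitrogen), with 1 probe set per gene, where fewer were tested, 367 and 121, and by group means 339 over both; the floor gave 489 with nitrogen. An estimated correlation gave 0 lists in the nitrogen response, 0 in the difference and 0 in the variety difference. The correlation of the responses was 0.0931 with no filter, 0.533 with the 60th percentile filter, 0.436 with the floor and 0.372 by Spearman. Probe sets changed the same and opposite ways were 2671 and 1883 with no filter, 387 and 25 with the 60th percentile filter, 3112 and 929 at 1.5-fold and 87 and 20 at 4-fold; opposite ones were 228 with median centring and 50 with the floor. Median centring left 4 lists in the difference of the responses, all higher. In the nitrogen response median centring, no filter and the floor each gave 7 lists, all higher, and quantile normalization gave 7 higher and 1 lower. Apart from the number tested or left out, the cause was not tested.

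Reversed values (log2) in the nitrogen response of both varieties were, with median centring, OsATG8a -0.26, OsATG8c -0.26 and OsGS1.2 -0.24, and with quantile normalization OsATG8a -0.17, OsATG8c -0.11, OsGS1.2 -0.19 and OsLBD37 0.0402. In the series matrix they were AP25 0.0356, OsSPX6 -0.93, OsLDH -0.0902, PBZ1 -0.0387, OsPR10b -0.79, RSOsPR10 -0.43, OsCPS2 -0.23, OsMAS -0.21, CYP76M7 -0.67, CYP76M8 -0.40, OsMCM5 0.18, OsCKX4 -0.0829, OsPIN1a 0.25, D17 0.0503 and OsGS1.2 -0.0311. Its reversed values in Varadan were OsTBT2 -2.43, OsMAS -1.35, PRXIIE-2 -0.77, OsPIP2.3 -0.49, CML27 -0.41, GRXS2 -0.64, OsPsbO -0.45, OsJAZ1 -0.96, DREB1G -3.57, OsPTR6 -0.44, OsCKX3 2.04, KIN12F 1.48, OsORC1 1.42, OsAPY3 0.73, OsFH6 2.501, OsBURP12 1.71, PCF6 1.57, AP25 1.502, OsAGO17 2.76 and OsAGP1 0.63. For the difference of the responses they were CYP99A3 -0.11, OsPsbO -0.24, OsTBT2 -3.98, OsCKX3 3.12, OsAPY3 0.54, OsFH6 2.95, OsBURP12 1.93, KIN12F 2.48, OsCAX1b 1.12, PCF6 1.90 and OsAGP1 0.67. The series matrix exchanges 2 arrays, which by construction changes these values. Some of them rest on readings below the 40th percentile of an array. With these raised, Varadan read -1.96 for DREB1G, 1.015 for OsCKX3, 1.36 for KIN12F, 0.68 for OsFH6, 1.006 for OsBURP12 and 1.28 for PCF6, and the difference 2.09 for OsCKX3, 1.14 for OsFH6, 1.23 for OsBURP12, 2.36 for KIN12F, 0.75 for OsCAX1b and 1.61 for PCF6, which are bounds. OsAGO17 (-0.0802) and OsSPX6 (0.00738) then did not reverse, so their reversal rests on such readings. Leaving out 1 array gave ranges of -5.10 to 0.0861 for OsHb1, -1.88 to 0.71 for OsNIA1, -0.83 to 0.15 for OsPIN1a, -0.99 to 0.30 for D17, -0.0743 to 0.16 for OsATG8a, -0.0308 to 0.12 for OsATG8c and -0.32 to 0.22 for OsLBD37. It reversed OsGS1.2 (-0.0285) and OsLBD37 (0.02) without replicate 1 of Prasanna with nitrogen. It also reversed OsHb1 and OsNIA1 without the Prasanna array lacking nitrogen, where the value is the response of Varadan alone. Without replicate 2 of Varadan it reversed OsATG8a (-0.02), OsATG8c (-0.01) and OsLBD37 (0.22). Without the Varadan array lacking nitrogen, where the value is the response of Prasanna alone, it reversed OsPIN1a, D17, OsATG8a, OsATG8c and OsLBD37 (0.08).

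Leaving out a lone array without nitrogen was not run for comparisons that need it. No paired analysis was possible because the labels give only the number 2 of a replicate and nothing pairs arrays across groups. The deposited tables hold no detection calls, so which weak readings lay above background is not known, and the results above give differences that rest on them as bounds.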
